A study of Homo sapiens with 6 samples.

How the data were processed

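RNA sequencing was measured in 6 libraries of NGP, a human neuroblastoma cell line. The labels place 3 libraries in a control group (Control) and 3 in a group with knockdown of CAMKV (CAMKV-KD), and name each library by its group and a replicate number. The sample descriptions name the groups sh-control and sh-CAMKV, where sh is the usual short form of short hairpin RNA. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made from total RNA with a SMARTer mRNA-Seq kit. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. They also do not say whether 1 or several knockdown reagents were used, and with 1 the comparison does not separate loss of CAMKV from other effects of that reagent.

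The deposited table holds whole-number counts per gene for the 6 libraries, with no normalization. Per the submitters' processing notes, the tools were FastQC 0.11.2, HISAT2 2.1.0 and StringTie 1.3.5, and the genome build was GRCh38.p13. FastQC reports read quality, HISAT2 aligns reads across splice junctions, and StringTie assembles and quantifies transcripts. The series' design text names DESeq2 1.28.1 for the authors' test and an over-representation test on a pathway portal. The strand setting, the annotation release and the way counts per gene were taken from StringTie (whole reads or a coverage estimate) are not given in the sources used here. Of the 19868 entries in the table, 14082 carry an identifier of a locus merged by StringTie and 5786 an Ensembl identifier, and each is paired with a gene symbol. In 847 loci, 2219 entries share a locus identifier with another symbol, so neighbouring or overlapping genes there can share reads. Without a stated strand setting, reads of a gene and of an antisense partner cannot be told apart. A further 126 entries share their symbol with another entry, and the one with the highest mean count carried the symbol. All 6 count columns were matched to a sample, and 3584 entries had no count in any library. Gene positions were taken from GENCODE release 29 on GRCh38 by symbol, which matched 97.0% of entries.

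Total counts per library ran from 20238281 to 24701564. At this depth, 3 counts in a library correspond to about 0.133 CPM (counts scaled to a common library total), the floor used for genes with no count in a whole group. No molecular identifiers are named in the labels, so such floors cover counting error only. Pairs of libraries were compared with a chi-square statistic over genes with a summed count of at least 10. It was 41.5 to 52.1 per degree of freedom within groups and 104.7 to 119.2 between groups, and no 2 libraries held identical values, so all 6 were kept as separate libraries.

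Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr, libraries were scaled by TMM (trimmed mean of M values), and the groups were compared with the quasi-likelihood F-test (glmQLFit, glmQLFTest) on 13366 genes with group as the only term. P-values were adjusted by the Benjamini-Hochberg method, and genes with adjusted p below 0.05 were called. Standard errors (SE) are the absolute log2 fold change divided by the square root of F. Expression levels are TMM-scaled CPM with the SD over 3 libraries.

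Gene lists were tested as groups with camera in limma 3.58.1 with a preset correlation of 0.01 between genes, adjusted over the 34 lists with at least 5 tested members. camera compares the members of a list with the other genes. The same test with a correlation estimated from the 6 libraries was an alternative, as were fry, which asks whether the members move on balance one way, and camera on ranks. The 36 lists covered the CaM kinase family and calmodulin, CREB-responsive and immediate early genes, CREB/CRTC and MAPK pathway components, MAPK feedback targets, MYCN and MYC targets, G1/S and DNA replication, G2/M and mitosis, p53 targets, apoptosis regulators, adrenergic and mesenchymal neuroblastoma identity, neuronal differentiation and cytoskeleton, synaptic vesicle and neurosecretion, axon guidance, ion channels, extracellular matrix and adhesion, TGF-beta, YAP/TAZ, Notch and WNT genes, the integrated stress response, the unfolded protein response, heat shock, hypoxia and glycolysis, cholesterol and fatty acid synthesis, nuclear-encoded oxidative phosphorylation, mitochondrially encoded mRNAs, cytosolic ribosomal proteins, type I interferon and NF-kappaB genes, nuclear-retained RNAs as a sign of RNA quality, and markers of Schwann and glial, fibroblast and stromal, blood and endothelial, and epithelial cells. The table used here holds no member of the list of nuclear-retained RNAs, which was not analysed here. Of the list members, 16 were matched through an older symbol.

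The design, the lists and the rule for naming genes were fixed before the data were examined. The rule named CAMKV, the 10 genes with the largest rise and the 10 with the largest fall among called genes with at least 10 CPM in the higher group and no overlap between groups, the 5 genes with the smallest p in each direction, the 4 members of each list with the smallest p, and 11 textbook hub genes. Clone-based, LOC, LINC, antisense, host-gene and small-RNA names were left out of the first selections. It gave 168 genes, 155 of them called. Some genes that the rule names are not reported here. A gene named outside the rule is said to be so where it appears.

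Alternatives were DESeq2 size factors, upper-quartile scaling and library totals, no filter and a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0 and limma-voom in place of edgeR, the replicate number as a block, each library left out in turn, the 20 most abundant and the mitochondrial genes left out, an adjusted p below 0.01, and a test against a fold of 1.2 (glmTreat). Chosen after seeing the data were robust estimation in edgeR, offsets that remove each library's trend with transcript length and GC content, and the use of loci with a single symbol only.

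The scripts were tested on simulated counts for the same 13366 genes and the comparison of CAMKV-KD with Control, with the means, library sizes and spread of these libraries and 200 genes changed. edgeR recovered 4.5% of genes changed by 1.5-fold, 34.3% of those changed by 2-fold and 68.2% of those changed by 4-fold, and 4.1% of its calls were false. With no gene changed it called 0 genes. In the same simulation 36.5% of the calls of DESeq2 and 5.3% of those of limma-voom were false. These shares depend on how many genes change. With 200 genes changed there and 4857 called here, they do not carry over to the real comparison. Each of the 4 list tests called a simulated shifted list and no other list. The simulated genes varied independently of each other, so this does not show how often correlated members give false list calls.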

Results

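The series asks how the transcriptome of NGP neuroblastoma cells changes when CAMKV is knocked down. CAMKV encodes a pseudokinase related to the calmodulin-dependent protein kinases that lacks the catalytic residues of an active kinase. Counts per gene were compared between 3 Control and 3 CAMKV-KD libraries. Total counts were 24701564, 22364742 and 22675342 in the Control libraries and 24274441, 20238281 and 21965871 in the CAMKV-KD libraries.

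CAMKV mRNA was lower in every CAMKV-KD library than in any Control library. Its level was 84.0, 77.3 and 84.6 CPM in the Control libraries and 25.4, 23.2 and 25.4 CPM in the CAMKV-KD libraries. The group means were 81.9 ± 4.05 CPM (SD, n = 3) and 24.7 ± 1.25 CPM (SD, n = 3), so 30.1% of the Control level remained. The log2 fold change was −1.73 ± 0.065 (SE), with an adjusted p of 0.000119 in edgeR's quasi-likelihood test. CAMKV (MSTRG.19050) is a protein-coding gene on the minus strand of chromosome 3, from 49857988 to 49870222 on GRCh38 in GENCODE 29. These values rest on 2032, 1684 and 1885 counts in the Control libraries and 629, 480 and 570 counts in the CAMKV-KD libraries.

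**Figure D1:**
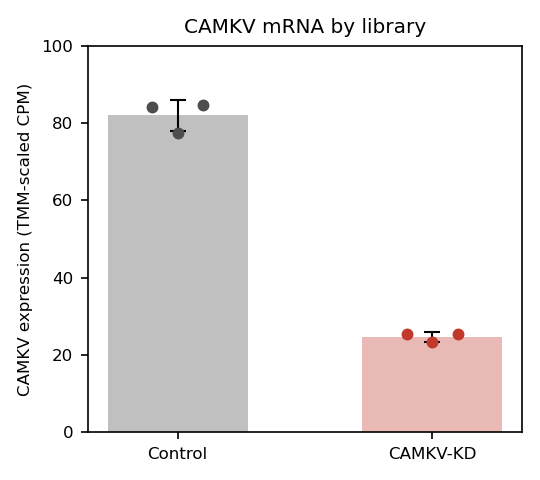
CAMKV expression in TMM-scaled CPM (vertical axis) for the Control and CAMKV-KD groups. Points are single libraries, bars are group means and error bars are SD (n = 3); the Control libraries sit between 77.3 and 84.6 CPM and the CAMKV-KD libraries between 23.2 and 25.4 CPM.

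Beyond CAMKV, 4857 of 13366 tested genes (36.3%) differed between the groups, with 2319 higher and 2538 lower in CAMKV-KD. Of these 4857 genes, 1104 changed at least 2-fold, 433 upward and 671 downward. The balance between directions depended on scaling: with library totals 2812 genes were higher and 2175 lower, and with upper-quartile scaling 2130 and 2698. The values of the groups did not overlap for 52.8% of tested genes, where chance gives 10%. The median log2 fold change of all tested genes was 0.0045.

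Among genes that met the rule for naming genes, the largest rise was in CXCL14, a secreted chemokine, at 4.21 ± 0.20 (log2 ± SE). Its level went from 1.32 ± 0.323 to 24.5 ± 1.03 CPM (SD, n = 3). CDH12, a cadherin of neural cells, rose by 3.69, and FEZF2, a transcription factor of cortical projection neurons, rose by 3.52. GNG13, a G protein gamma subunit, rose by 3.41, IQGAP2, a scaffold protein, by 3.36, and RPH3A (rabphilin), a binding partner of synaptic RAB3 proteins, by 2.99. DENND4B rose by 2.83 and TH, the rate-limiting enzyme of catecholamine synthesis, by 2.62 ± 0.23 (SE). HNRNPA1L2 (3.19) and SH2B3 (2.59) also met the rule, but the first has a near-identical relative in HNRNPA1 and counts of 251, 66 and 389 in the CAMKV-KD libraries. Leaving out a library ended the call of HNRNPA1L2 in 2 of 6 fits (Control 2 or Control 3, adjusted p up to 0.0609), as did limma-voom, and that of SH2B3 in 5 of 6 fits (all but the one without Control 3, adjusted p up to 0.0785).

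Among genes that fell, DIAPH2, a formin, and KIAA1644 had no count in any CAMKV-KD library. Against a floor of 3 counts per library they were at least 152-fold and at least 91.2-fold lower than their Control means of 20.2 and 12.2 CPM. GPR155 was counted in only 1 of the CAMKV-KD libraries, with 9 counts there and 1019, 1018 and 383 counts in the Control libraries; its log2 fold change was −7.99, and −12.65 without CAMKV-KD 3, a fit with no CAMKV-KD count left. TCP11L2 fell by 4.83 and NDUFA4L2, a mitochondrial protein induced in hypoxia, by 4.22 ± 0.17 (SE). CXorf38 (−3.79), CA12 (−3.24), a membrane carbonic anhydrase, RAB26 (−3.23), a small GTPase of secretory granules, and TEX19 (−3.15) fell as well. AKAP6 (−3.50) lost its call in 4 of 6 fits that left out a library (Control 2, Control 3, CAMKV-KD 1 or CAMKV-KD 3, adjusted p up to 0.103).

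The genes with the smallest p in each direction had little spread between replicates. Selection by p favours such genes, so their SDs and SEs may be too small. FN1 (fibronectin, a matrix protein) rose by 2.42 ± 0.031 (log2 ± SE), from 145.6 ± 4.42 to 776.5 ± 1.73 CPM (SD, n = 3; adjusted p = 2.11e-05, edgeR). RGL1 rose by 1.53, SPRY4, a feedback inhibitor of receptor tyrosine kinase signalling, by 1.305, IGFBP5 by 1.003 and FLT1, a receptor of vascular endothelial growth factors, by 1.74. TXNIP, a thioredoxin-binding arrestin that restrains glucose uptake, fell by 1.88 ± 0.026 (SE), from 622.9 ± 5.72 to 168.8 ± 3.29 CPM (SD, n = 3; adjusted p = 2.11e-05, edgeR), and its relative ARRDC4 fell by 1.88. NEUROD1, a proneural transcription factor whose locus is shared with another symbol, fell by 2.43, BNIP3 by 1.67 and CDK6, a G1 kinase, by 1.46.

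Of the 34 lists tested as groups, 14 were called by camera, 7 higher and 7 lower in CAMKV-KD. With a correlation estimated from the libraries, 3 of them kept their call: G1/S and DNA replication, hypoxia and glycolysis, and cytosolic ribosomal proteins. A lost call does not by itself show correlated members. The estimate was below the preset 0.01 for the neuronal (0.001), synaptic (−0.025), ion channel (0.005) and apoptosis (−0.021) lists. For the other lists that lost their call it ran from 0.011 (nuclear-encoded oxidative phosphorylation) to 0.933 (mitochondrially encoded mRNAs). For 19 of 35 lists with tested members, the counts of members that rose and fell were the same when adjusted over the list alone, and for the others both counts are given.

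**Figure D2:**
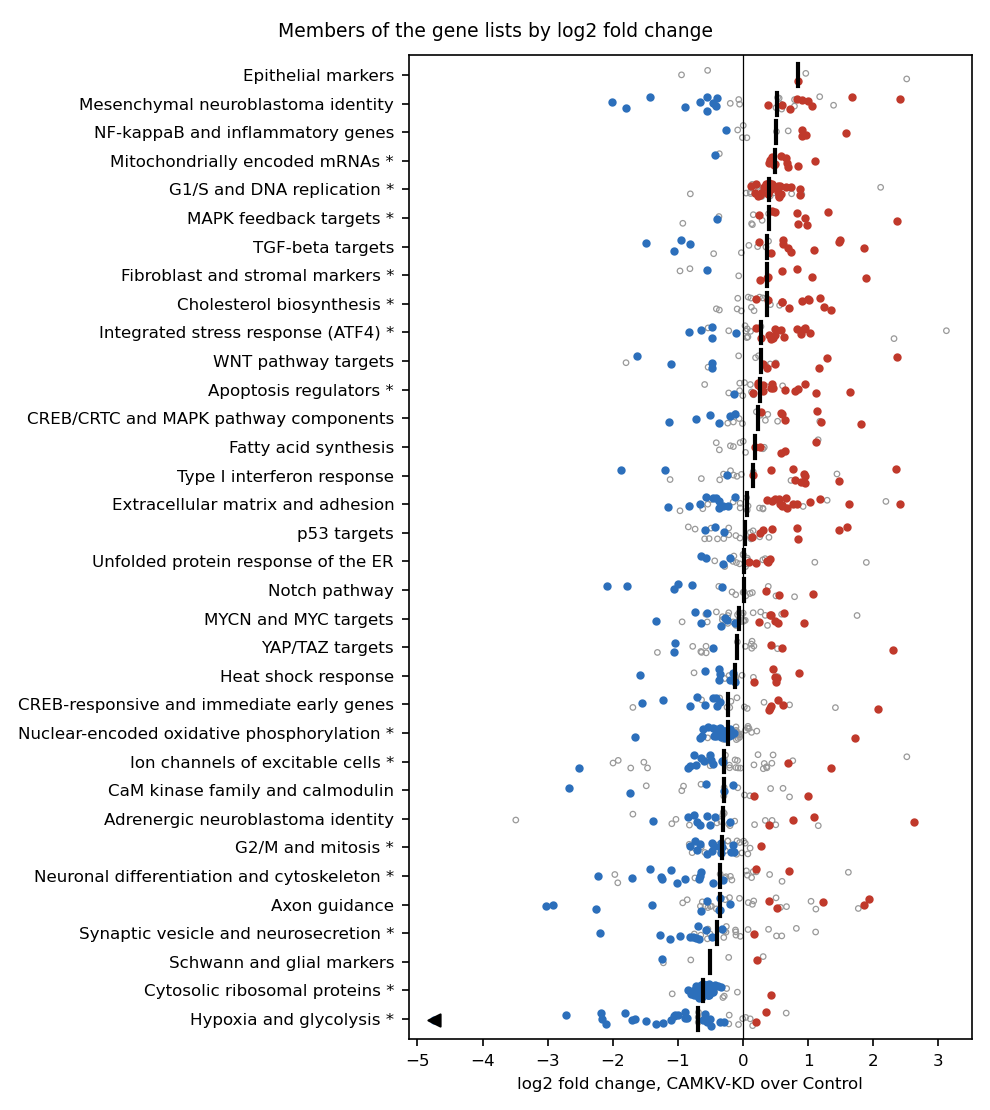
Log2 fold change (horizontal axis, CAMKV-KD over Control) of each tested member of 34 gene lists, ordered by median. Red and blue points are members that rose or fell at an adjusted p below 0.05, open points are the others, vertical bars are list medians, asterisks mark the 14 lists called by camera, and the black triangle is CA9 at the bound set by a floor of 3 counts per library; ribosomal protein genes form a narrow cluster around −0.62, and hypoxia and glycolysis has the lowest median, −0.69.

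Genes of the neuronal phenotype fell as groups. In the list of neuronal differentiation and cytoskeleton genes, 13 of 31 members fell and 2 rose (median −0.35; camera adjusted p = 0.000501, and adjusted p = 0.0714 with an estimated correlation). NGFR, the low-affinity neurotrophin receptor, fell by 2.22 ± 0.091 (SE), the microtubule-associated protein tau gene MAPT by 1.70 ± 0.066 (SE), and the neurofilament genes NEFM and INA by 1.01 and 0.66. Among synaptic vesicle and neurosecretion genes 12 of 32 fell and 1 rose (median −0.41; camera adjusted p = 0.00101, and adjusted p = 0.0714 with an estimated correlation). RAB3A, a GTPase of synaptic vesicles, fell by 2.19, and SCG3 and CPE, of the secretory granule, by 0.72 and 0.69. Ion channel genes of excitable cells had 12 of 41 members lower and 2 higher (median −0.29; camera adjusted p = 0.0395, and adjusted p = 0.168 with an estimated correlation). The sodium channel gene SCN1A fell by 2.53 and HCN2, of a pacemaker channel, by 0.84. This list lost its call without Control 1 (adjusted p = 0.0568) or Control 3 (adjusted p = 0.0776).

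The list of the adrenergic state, the sympathetic neuron-like state of neuroblastoma cells, was not called. PHOX2A, a transcription factor of that state, fell by 0.66, whereas TH, in the same list, rose. Of its 31 members 9 fell and 4 rose, and 10 fell and 4 rose adjusted over the list alone (median −0.31; camera adjusted p = 0.152). DBH, a later enzyme of noradrenaline synthesis, was at 0.18 ± 0.17 (SE), between 0.023 (without CAMKV-KD 3) and 0.28 (without Control 1) when a library was left out, and did not pass. MYCN did not pass either: it was at −0.34 ± 0.24 (SE) with Control counts of 22795, 33777 and 19102, and lay between −0.50 (without Control 3) and −0.028 (without Control 2). Axon guidance genes moved both ways, with 10 of 37 lower and 5 higher, and 13 and 5 adjusted over the list alone (median −0.36, between −0.38 and −0.21 over the alternatives; camera adjusted p = 0.366). The semaphorin receptor genes PLXNA4 and PLXNA2 rose by 1.93 and 1.22, while PLXND1 and the ephrin gene EFNB3 fell by 0.65 and 1.40.

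The mesenchymal list, genes of the opposite neuroblastoma state, was split between directions: 9 of 32 members rose and 10 fell, and 12 and 11 adjusted over the list alone (median 0.52, between 0.17 and 0.58 over the alternatives; camera adjusted p = 0.476). FN1 led the rises together with PRRX1, a mesenchymal transcription factor, at 1.67 ± 0.080 (SE) and COL3A1 at 0.83. Extracellular matrix and adhesion genes were likewise mixed, with 15 of 45 higher and 11 lower, and 15 and 12 adjusted over the list alone (median 0.063, between 0.016 and 0.12 over the alternatives; camera adjusted p = 0.293). FBN1 (fibrillin) rose by 1.63 and the integrin gene ITGAV by 0.67. Fibroblast and stromal markers, 8 of whose 11 tested members stand in other lists too, had 7 members higher and 1 lower (median 0.36; camera adjusted p = 0.0429, and adjusted p = 0.402 with an estimated correlation). ACTA2 (smooth muscle actin) rose by 1.89 and COL1A1 by 0.59, and 8 of the 11 reached 10 CPM in Control libraries. The call was lost without Control 2 (adjusted p = 0.115), Control 3 (adjusted p = 0.0609) or CAMKV-KD 2 (adjusted p = 0.0728), under scaling by library totals (adjusted p = 0.0653), with camera on ranks (adjusted p = 0.0942), and with length and GC offsets chosen after seeing the data (adjusted p = 0.0684). It was also lost with the replicate number as a block.

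Markers of other cell types were few. Schwann and glial markers had 1 of 6 members higher and 1 lower (median −0.51, between −0.72 and −0.29 over the alternatives; camera adjusted p = 0.524). L1CAM, which is also in the neuronal list, fell by 1.24, and PMP22 was at 0.22, a call that was lost in 5 of 6 fits that left out a library (all but the one without Control 2, adjusted p up to 0.0765). Of 5 epithelial markers, 1 was higher, and 2 were adjusted over the list alone (median 0.84; camera adjusted p = 0.524). That gene, MUC1, was at 0.84 and was not called in any of the 6 fits without a library. KRT7 was at 2.51 (adjusted p = 0.0536, edgeR), and was called without Control 1 (1.92, adjusted p = 0.046) or Control 3 (3.65, adjusted p = 0.0395). Only 3 of 13 blood and endothelial markers passed the filter, which is too few for a group test. KDR, a receptor of vascular endothelial growth factors, rose by 2.07 to 17.6 ± 0.548 CPM (SD, n = 3), the only riser of the 3, and 2 rose adjusted over the list alone (median 0.74). CDH5 was at 0.66 CPM and HBA2 at 0.27 CPM in CAMKV-KD.

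**Figure D3:**
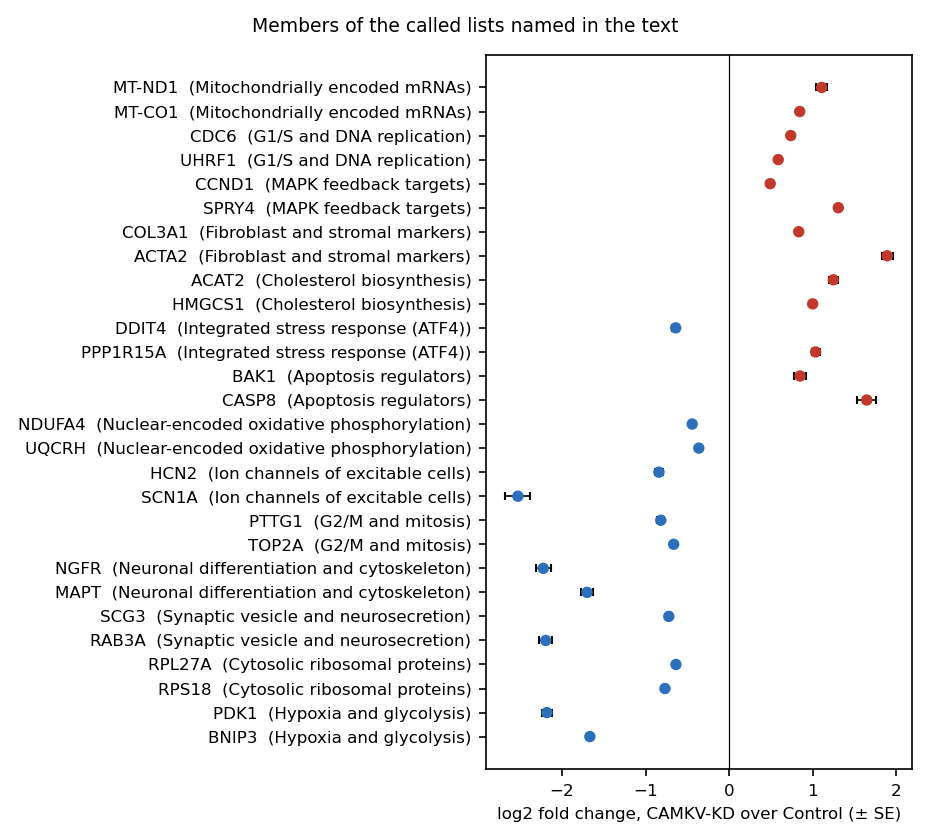
Log2 fold change (CAMKV-KD over Control, horizontal axis) with its standard error for the genes named in the text that had the smallest p, up to 2 from each of the 14 called lists, with the list in parentheses. Red points rose and blue points fell; SCN1A (−2.53), NGFR (−2.22) and RAB3A (−2.19) lie lowest, and ACTA2 (1.89) and CASP8 (1.64) highest.

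Hypoxia and glycolysis genes showed the lowest median of the 34 lists. Of 38 members 25 fell and 2 rose, and 28 fell and 2 rose adjusted over the list alone (median −0.69; camera adjusted p = 1.86e-09, and adjusted p = 0.0352 with an estimated correlation). PDK1, the kinase that holds pyruvate dehydrogenase inactive, fell by 2.18 ± 0.061 (SE), NDRG1 by 2.11, PGK1, a glycolytic enzyme, by 1.81, from 931.7 ± 22.6 to 264.9 ± 23.2 CPM (SD, n = 3), and BNIP3, a mitophagy receptor, by 1.67. The 2 members that rose were SLC2A1 at 0.35 and HK2 at 0.20, and VEGFA, at −0.070, was among the 11 members not called. SLC2A1, HK2 and VEGFA were named after their values were seen. CA9, a carbonic anhydrase induced in hypoxia, was also named after its values were seen. It had no count in CAMKV-KD libraries and was at least 26.7-fold lower than its Control mean of 3.57 CPM. The list median is −0.69 with CA9 at that bound too, and it could not differ, since the fitted value and the bound both lie below it.

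Respiratory chain mRNAs moved in opposite directions by the genome that encodes them. Nuclear-encoded members fell, 26 of 47 against 1 that rose (median −0.235; camera adjusted p = 2.24e-05, and adjusted p = 0.0714 with an estimated correlation). With the length and GC offsets, chosen after seeing the data, the median was −0.14 and the list was still called (adjusted p = 0.00157). Examples are COX7C at −0.63, NDUFB5 at −0.47, NDUFA4 at −0.44 and UQCRH at −0.36. Of the 13 mitochondrially encoded mRNAs, 11 rose and 1 fell (median 0.49; camera adjusted p = 8.49e-05, and adjusted p = 0.435 with an estimated correlation). MT-ND1 rose by 1.11 and MT-CO1 by 0.84 ± 0.028 (SE). Mitochondrial genes took 1.90, 1.86 and 1.67% of counts in the Control libraries and 2.92, 2.70 and 2.90% in the CAMKV-KD libraries.

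Cytosolic ribosomal protein mRNAs fell together, 53 of 61 members against 1 that rose (median −0.62; camera adjusted p = 5.1e-24, and adjusted p = 0.0313 with an estimated correlation). RPS18 fell by 0.77 ± 0.019 (SE), from 1911 ± 14.5 to 1122 ± 18.4 CPM (SD, n = 3), RPL27A by 0.64, RPL10A by 0.64 and RPL15 by 0.56. Their share of all counts was 8.58, 8.41 and 8.69% in the Control libraries and 5.91, 5.89 and 5.95% in the CAMKV-KD libraries. MYCN and MYC targets, a list of ribosome biogenesis and metabolic genes, moved both ways, with 7 of 44 higher and 8 lower (median −0.062, between −0.089 and −0.0026 over the alternatives; camera adjusted p = 0.663). The transferrin receptor gene TFRC rose by 0.63 and UTP20 by 0.54, while PPAT and SHMT2, of purine and one-carbon metabolism, fell by 0.65 and 0.55.

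Cell cycle genes split by phase. Of 40 G1/S and DNA replication genes 25 rose and none fell, and 28 rose adjusted over the list alone (median 0.40; camera adjusted p = 5.67e-09, and adjusted p = 0.0313 with an estimated correlation). MCM5 and MCM6, of the replicative helicase, rose by 0.87 and 0.32, CDC6, which loads it, by 0.74, and UHRF1 by 0.59. Of 36 G2/M and mitosis genes 15 fell and 1 rose (median −0.33; camera adjusted p = 0.000349, and adjusted p = 0.125 with an estimated correlation). PTTG1 (securin) fell by 0.82, HMMR by 0.70, TOP2A (topoisomerase II alpha) by 0.66 ± 0.026 (SE) and the mitotic kinesin gene KIF20A by 0.48. MKI67, a proliferation marker, was at −0.093 ± 0.12 (SE) and did not pass; it was −0.0037 without Control 1 (adjusted p = 0.985), and was called at −0.22 without Control 3 (adjusted p = 0.0352).

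Apoptosis regulators were higher in 16 of 28 cases and lower in 1 (median 0.26; camera adjusted p = 0.000592, and adjusted p = 0.0714 with an estimated correlation). The members that moved include both promoters and inhibitors of cell death: CASP8, an initiator caspase, rose by 1.64, BAK1 and BID, which promote mitochondrial permeabilization, by 0.85 and 0.46, and MCL1, which opposes it, by 0.27. Of 28 p53 targets 8 rose and 3 fell, and 8 and 4 adjusted over the list alone (median 0.031, between −0.016 and 0.11 over the alternatives and below 0 without Control 1 or Control 2; camera adjusted p = 0.545). GDF15 rose by 1.59, PLK2 by 0.85 and SESN2 by 0.83, while GADD45A and CDKN1A, the p21 cell cycle inhibitor gene, fell by 0.43 and 0.29. MDM2 was at 0.40 ± 0.16 (SE) and did not pass; it was 0.27 without Control 1, and was called at 0.55 without Control 3 (adjusted p = 0.0472).

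In the CaM kinase family and calmodulin list, which contains CAMKV itself, 5 of 19 members fell and 2 rose, and 5 and 3 adjusted over the list alone (median −0.29, and −0.11 without Control 1, −0.18 without Control 3, −0.17 without CAMKV-KD 2 and −0.15 without CAMKV-KD 3; camera adjusted p = 0.399). The calmodulin genes CALM3 and CALM2 fell by 0.30 and 0.16, and DAPK1 was at 0.17, a call lost in 5 of 6 fits that left out a library (all but the one without CAMKV-KD 2, adjusted p up to 0.0656). CREB-responsive and immediate early genes had 9 of 28 members lower and 6 higher (median −0.23; camera adjusted p = 0.403). JUN rose by 0.54, while the activity-regulated gene ARC fell by 1.24, the kinase gene SIK1 by 0.81 and FOSL2 by 0.42, and FOS was at 0.32 ± 0.26 (SE) without passing, between 0.11 (without Control 2) and 0.49 (without Control 1). Components of the CREB/CRTC and MAPK pathways moved both ways, with 7 of 24 higher and 6 lower (median 0.24, and 0.056 without Control 1, 0.36 without Control 3 and 0.15 without CAMKV-KD 2; camera adjusted p = 0.482). The phosphodiesterase gene PDE4B rose by 1.80, PRKACB, a catalytic subunit of protein kinase A, by 1.13 and the coactivator gene EP300 by 0.64, MAPK3 (ERK1) fell by 1.14, and CREB1 was at 0.53 ± 0.31 (SE) without passing, between 0.24 (without CAMKV-KD 2) and 0.77 (without Control 2). MAPK feedback targets rose in 9 of 17 cases and fell in 1, and in 11 and 1 adjusted over the list alone (median 0.39; camera adjusted p = 0.000693, and adjusted p = 0.115 with an estimated correlation). Besides SPRY4, the transcription factor gene ETV4 rose by 0.95, SPRY2 by 0.84 and CCND1 (cyclin D1) by 0.49 ± 0.023 (SE).

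Developmental signalling lists were not called. TGF-beta targets had 10 of 20 members higher and 4 lower (median 0.37; camera adjusted p = 0.0995), with ID3 and ID2 at 1.08 and 0.69 and KLF10 and TGFB2 at −0.95 and −1.06. YAP/TAZ targets had 3 of 19 higher and 3 lower (median −0.089, between −0.46 and −0.026 over the alternatives, with −0.30 without Control 2 and −0.29 without CAMKV-KD 1 or CAMKV-KD 3; camera adjusted p = 0.524), with IGFBP3 at 2.31, from 87.5 ± 8.62 to 432.8 ± 76.9 CPM (SD, n = 3). Notch pathway genes had 6 of 20 lower and 3 higher, and a median of 0.0081 that lay between −0.056 and 0.096 over the alternatives (−0.019 under upper-quartile scaling), while their mean (−0.19) and the test pointed down (camera adjusted p = 0.524). HEY1 and HES1, target genes of the pathway, rose by 1.07 and 0.54, and the ligand gene DLL3, the modifier gene LFNG and HES6 were lower, at −1.05, −2.09 and −0.996. WNT pathway targets had 6 of 18 higher and 4 lower, and 7 and 4 adjusted over the list alone (median 0.27; camera adjusted p = 0.316). LGR5 and SFRP1 rose by 1.29 and 0.36, and ZNRF3 fell by 0.48.

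Cholesterol biosynthesis genes rose, 11 of 25 members with none lower, and 14 adjusted over the list alone (median 0.36; camera adjusted p = 0.000285, and adjusted p = 0.121 with an estimated correlation). HMGCS1, a synthase of the early pathway, rose by 0.998 ± 0.031 (SE), from 348.4 ± 10.5 to 696.0 ± 11.7 CPM (SD, n = 3), and ACAT2 by 1.25. In fatty acid synthesis 5 of 15 members rose and none fell (median 0.18, between 0.10 and 0.25 over the alternatives; camera adjusted p = 0.115). The desaturase genes FADS2, FADS1 and SCD rose by 1.12, 0.64 and 0.25, and ELOVL1 by 0.58.

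Genes of the integrated stress response rose in 14 of 30 cases and fell in 5, and in 15 and 5 adjusted over the list alone (median 0.28; camera adjusted p = 0.00338, and adjusted p = 0.168 with an estimated correlation). PPP1R15A (GADD34) rose by 1.03 and DDIT3 (CHOP) by 0.89, while DDIT4 and STC2, which also respond to hypoxia, fell by 0.64 and 0.48. The unfolded protein response list had 5 of 26 members higher and 4 lower, and 5 and 5 adjusted over the list alone. Its median was 0.020, but −0.0062 under upper-quartile scaling (camera adjusted p = 0.92). DNAJB11 and DNAJC3 rose by 0.41 and 0.36, and CREB3L2 and PDIA6 fell by 0.57 and 0.31. Heat shock genes had 8 of 22 members lower and 6 higher, and 8 and 7 adjusted over the list alone (median −0.12, between −0.15 and −0.060 over the alternatives; camera adjusted p = 0.524), with HSPA4L at −1.58 and DNAJB1 and DNAJA1 at 0.53 and 0.48. Type I interferon response genes had 10 of 24 higher and 3 lower (median 0.16, between −0.019 and 0.53 over the alternatives and 0.31 without Control 2; camera adjusted p = 0.304). SAMD9 and IFITM3 rose by 2.35 and 0.77, and BST2 and IFI6 were lower, at −1.88 and −1.198. Of 11 NF-kappaB and inflammatory genes 4 rose and 1 fell (median 0.51, and 0.30 without Control 3 and 0.27 without CAMKV-KD 3; camera adjusted p = 0.146), with IRF1 at 1.58, NFKBIA at 0.97, BCL3 at 0.90 and SOD2 at −0.26.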

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

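Robust estimation, the length and GC offsets and the restriction to loci with a single symbol were chosen after seeing the data. CAMKV kept its direction and its call in all 19 alternatives, between −1.78 and −1.67 on the log2 scale (adjusted p up to 0.0102), and the count of genes changed at least 2-fold stayed within 1.5 times the reported one. The 2319 higher genes became 1273 at an adjusted p below 0.01 and 1194 against a fold of 1.2, and the 2538 lower genes became 1561 and 1484, by the stricter thresholds themselves. With the replicate number as a block the higher genes were 1526 in edgeR and 1426 in DESeq2. The numbers do not pair the libraries: same-numbered libraries deviated from their group means with correlations of −0.01, −0.062 and −0.032, and the block lowers the residual degrees of freedom. With it the fibroblast and stromal list lost its call (adjusted p = 0.0778). Without 1 library, higher genes numbered 1739 to 1925 and lower genes 2044 to 2119, and 74.6 to 77.0% of all calls remained in the same direction. DESeq2 called 5699 genes, among them 99.4% of the edgeR calls. Of 14 called lists, 3 were called with an estimated correlation, while fry, which does not compare a list with other genes, called 28; without 1 library 12 to 14 were called. The unfolded protein response list changed direction in its test with medians of −0.0062 under upper-quartile scaling, 0.0197 without CAMKV-KD replicate 2 and 0.0202 with fry, beside 0.0087 without Control replicate 1 and 0.0295 without CAMKV-KD replicate 3, where the direction stayed; the cause was not tested. No named gene that was called changed direction in any of these alternatives, while 6 lost their call without some library, 8 with the block in DESeq2, 4 with the block in edgeR and 1 in limma-voom. In simulations at this depth and spread, with 200 genes changed, 34.3% of genes changed by 2-fold were recovered. Changes of that size can thus be missed. The rate itself does not carry over to these data, where far more genes were called.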

Other observations

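In this part, the lists of proteasome, mitochondrial ribosomal protein, MHC class I, translation factor and other 5' TOP genes were chosen after the main results were seen, and the tests of depth, of all genes under library totals, of glycolytic enzymes alone and of VEGF genes after the result they measure was seen. PSMD12, PSMD11, PSMB10 and VEGFA lie outside the rule for naming genes and were chosen after their values were seen. Proteasome subunit mRNAs rose in 16 of 31 cases and fell in none (median 0.17; camera adjusted p = 4.09e-05 over the added lists, and adjusted p = 0.123 with an estimated correlation), with PSMD12 at 0.50 and PSMD11 at 0.55. The idea that large housekeeping complexes fall as the cytosolic ribosome does was not borne out for the proteasome by this median of 0.1707. Nuclear-encoded oxidative phosphorylation genes did fall, with 26 of 47 lower and 1 higher (median −0.235). Mitochondrial ribosomal protein mRNAs, with 14 of 77 lower and 6 higher, had a median of −0.0463, far from the −0.62 of the cytosolic ones (camera adjusted p = 0.468).

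Antigen presentation genes were examined for a rise, and VEGF genes for receptors and ligand moving in opposite directions. Of 11 tested MHC class I pathway genes none rose and 2 fell, among them PSMB10 at −0.63, with a median of −0.0702 (camera adjusted p = 0.281), so the hypothesis of a rise gained nothing, although a missed threshold does not exclude it. The receptor genes FLT1 and KDR were higher while the ligand gene VEGFA was at −0.0701 ± 0.035 (SE; adjusted p = 0.182, edgeR), which leaves open whether the ligand changed.

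Replicates of a group differed widely at some well-counted genes. Among 9817 genes with a mean of at least 200 counts, 549 (5.6%) had a within-group SD above 1 on the log2 scale, and 1.1% of these were called, against 41.3% of the others. The share was lower, at 2.67% (95% exact interval 2.25 to 3.15), among genes with a mean of at least 1000 counts, so depth may contribute. Low depth alone does not account for the spread, since these well-counted genes still showed it. The sharing of a locus between symbols does not account for it either. It applied to 12.9% (10.2 to 16) of the high-spread genes and 11% of all. Division of reads between transcripts of a gene stays open. With a mean count of 200 to 5000, the share was 4.39% (3.14 to 5.95) among genes with 1 or 2 annotated transcripts. It was 5.87% (5.2 to 6.61) among those with 3 to 9 and 6.34% (5.57 to 7.18) among those with 10 or more. The share thus rose with the number of transcripts, but the intervals of the lowest and highest class overlap. Overlap does not test the difference, and no direct test was run. How counts were taken from assembled transcripts is not given in the sources used here, and no biological explanation was tested.

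The fall of ribosomal protein mRNAs was weighed against technical trends. In 10000 draws of other genes matched on length, GC content and expression, the median was −0.042 and the lowest draw −0.27, which argues against a length or GC trend. Leaving out the 20 most abundant and the mitochondrial genes before scaling (ribosomal median −0.6204) took the median of all tested genes only from 0.0045 to 0.0031 and so decides nothing, but a few genes taking counts from all others would lower the typical gene under scaling by library totals, where the median of all tested genes was 0.0642. Other mRNAs with a 5' terminal oligopyrimidine (TOP) motif, which share translational control with ribosomal protein mRNAs, had a median of −0.4792, with 15 of 20 lower and none higher (camera adjusted p = 1.29e-06, and adjusted p = 0.033 with an estimated correlation), while translation factors outside that class had a median of 0.11. A candidate explanation is a lower abundance of TOP mRNAs as a class in CAMKV-KD cells, a hypothesis found and tested on the same libraries. Growth conditions that differ between the groups were not tested for this pattern.

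The fall of hypoxia and glycolysis genes was not restricted to glycolytic enzymes, since the other members had a median of −0.7867. Scaling does not account for it either: the list median was at most −0.6278 under the 3 scaling alternatives. A difference in oxygen, density or medium between the cultures of the groups cannot be told apart from an effect of the knockdown, because such a difference may be the same in the 3 libraries of a group. Within groups the library medians of the list ranged over at most 0.171 on the log2 scale. The knockdown itself remains among the open explanations.

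The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. Only the real split (1 of 10) gave as many calls: 4857 genes against at most 0 in the other splits, 1104 genes changed at least 2-fold against at most 0, and 14 lists against at most 7. Every other split puts Control and CAMKV-KD libraries on both sides. A difference between the real groups then widens the spread within each side, which makes gene calls unlikely from the start. It can also leave part of that difference between the sides, so these counts do not measure false calls.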
